A study of Mus musculus with 6 samples.

How the data were processed

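The series holds single-cell and single-nucleus RNA libraries of PB3, a mouse mammary tumour cell line, made in 3 runs. Run 1 gave 1 library of untreated cells (UNT cells) and 1 of cells after 4 rounds of eribulin (ERI4 cells). Run 2 gave 2 libraries, each of 3 conditions that were labelled with hashtag oligos and captured together: 1, 2 and 3 rounds of eribulin (ERI1, ERI2 and ERI3) and 1, 2 and 3 rounds of paclitaxel (PAC1, PAC2 and PAC3). Run 3 gave the RNA part of a combined RNA and chromatin assay on nuclei, again untreated (UNT nuclei) and after 4 rounds of eribulin (ERI4 nuclei). An eribulin round was 500 nM for 72 h with 48 h of recovery. The first paclitaxel round was 100 nM for 72 h with 48 h of recovery before the next, and later rounds were 250 nM. After the last paclitaxel round the labels name no recovery for PAC2 and give no length of it for PAC1 and PAC3. The cells carried lentiviral lineage barcodes, short synthetic sequences that integrate into the genome and are passed to daughter cells.

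Per the series' design text and the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 3.1.0 for run 1, Cell Ranger 4.0.0 for run 2 and Cell Ranger ARC 1.0.0 for run 3, cells were filtered, clustered and embedded with Seurat 3.1.4, and pseudotime was computed with Monocle3 0.2.1 on all samples together, with untreated cells as the root. The stated filter removed cells with under 200 genes and cells with over 50% of UMIs (counted RNA molecules) in mitochondrial or in ribosomal genes. No gene expression matrix was analysed here. What was analysed is the authors' table of 51785 cells, their UMAP coordinates and the barcode sequence lists. In that table the deposited counts are UMIs per cell, genes per cell, barcode counts per cell and the number of different barcodes detected per cell, without normalization. The deposited percent values are the shares of a cell's UMIs in mitochondrial and in ribosomal genes; the ribosomal values reach no more than 1.92%, and are not used further. The deposited score columns hold S and G2M phase scores for runs 1 and 2, and pseudotime for all cells; their scales are arbitrary. Cluster numbers and barcode calls were taken as the authors deposited them. In all, 179 of the 12766 cells of run 2 fell outside the stated filter and were kept. Doublets were handled only through the deposited barcode calls. These name only some of the cells with several detected barcodes. Of UNT cells, 59.5% had 2 or more, and the latest of the calls named 12.3% Doublet and 3.72% Multiplet. No doublet caller was run, and the table has no class for hashtag doublets.

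Each cell was given a condition from the deposited condition name, after its library had been matched to the labels. Another column of names in the table calls the run 1 eribulin library ERI1, where the labels give it 4 rounds, and was not used. Every condition has 1 library. Cells are not replicates of a treatment, so no test was made and no p-value is given; values are set side by side. A share of cells stands with its exact Clopper-Pearson 95% interval in parentheses, and a share of 0 with the share that 3 cells would make. These intervals and limits cover counting error only, not the spread between cultures. Comparisons were made within a run: ERI4 against UNT cells, ERI4 against UNT nuclei, successive rounds within each drug, and eribulin against paclitaxel after the same number of rounds. Run 2 has no untreated library, so its conditions and the untreated ones differ in run as well as in drug, and are given only as levels. The clusters were made by the authors on all libraries together, so a cluster filled mostly by 1 library may be that library and not a cell state. Cell counts per gene were not at hand, so cells could not be thinned to equal depth; a window of UMI counts common to the conditions compared (from the highest 10th percentile to the lowest 90th percentile) was used instead.

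The table holds no phase call, so the phase was set from the deposited scores: G1 where both were at or below 0, otherwise the phase with the higher score. For pseudotime the medians were compared, with the share of random pairs of cells in which the first condition was higher. Mixing in the UMAP was measured on 848 cells drawn from each condition, as the share of the 30 nearest neighbours that came from each condition. The table holds 3 successive barcode calls per cell; the latest was used, a choice made after seeing the data. The first revision gave the same barcode as the latest call in at least 99.7% of the cells called in both, except in the ERI4 nuclei, where it gave the same barcode in 34.1% of 939 nuclei and called 1909 nuclei in which no barcode was detected. Every nucleus of run 3 has at least 1 barcode feature, unlike the cells, so 1 was subtracted there from the number of detected barcodes. A barcoded cell is a cell with 1 called barcode, which can be 1 of several detected. Of UNT cells, 5.77% had exactly 1 detected barcode and 46.0% had 1 called barcode. Diversity was measured on 569 barcoded cells drawn without replacement from each condition, 1000 times, and is given with the range of the central 95% of the draws; PAC2 has exactly 569 barcoded cells and so no such range. The link between barcode and cluster is the share of pairs of cells with the same barcode in the same condition that lie in the same cluster, beside its mean over 100 shuffles of the clusters within the condition. The measure was tested on simulated clusters for the 2215 barcoded ERI3 cells: it gave 30.6% for a true value of 31.1% without a link, and 88.3% for a true value of 89.0% with one.

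Barcodes are named by a rule set before the data were examined: the 5 with the most cells in the conditions of each comparison, 16 barcodes in all. Clusters are named where they hold at least 5% of the cells of some condition; the lists of genes and cell type markers fixed beforehand could not be used without gene values. A barcode is written as the authors name it, by its first part (bc14) and second part (bc30). The full list holds 10000000 sequences of 48 bases, made of 100 first parts of 14 bases, the linker TGGT and 100000 second parts of 30 bases, and all 697 barcodes called in the table are in it. The barcodes are synthetic and their places in the mouse genome were not measured. The barcode list of run 2 holds the 6 hashtags and 185 barcodes; of the 237 barcodes called in run 2, 155 are in that list. Alternatives fixed beforehand were stricter gene and mitochondrial filters, the common depth window, other numbers of neighbours, other summaries of pseudotime, and other rules for counting barcodes; the other barcode calls, the authors' stated filter and the removal of cells called Doublet or Multiplet were added after seeing the data. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.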

Results

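Eribulin, which blocks the growth of microtubules, and paclitaxel, which stabilises them, were given in repeated rounds to barcoded PB3 mouse mammary tumour cells, to follow the cells' states and lineages under treatment. The deposited table holds 11061 UNT cells and 9331 ERI4 cells from run 1, 1865 ERI1, 1257 ERI2 and 3076 ERI3 cells and 2928 PAC1, 848 PAC2 and 2792 PAC3 cells from run 2, and 9916 UNT nuclei and 8711 ERI4 nuclei from run 3. Depth differed between conditions. The median was 18420 UMIs per cell in UNT cells and 20877 in ERI4 cells. In run 2 it was 17297 in ERI1, 17285 in ERI2 and 16775 in PAC2, but 11267 in ERI3, 11674 in PAC1 and 12776 in PAC3. Nuclei were shallower, with medians of 3428 UMIs in UNT nuclei and 2089 in ERI4 nuclei. The median mitochondrial share was between 2.60% and 4.70% in the cell conditions, 9.43% in UNT nuclei and 12.8% in ERI4 nuclei. There were no replicate libraries, so no difference below has been set against the spread between cultures.

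After 4 rounds of eribulin, cells occupied other clusters than untreated cells. Clusters 1, 5 and 6 together held 93.8% (93.3 to 94.2) of UNT cells and 1.29% (1.07 to 1.54) of ERI4 cells. Clusters 2, 3, 8 and 12 held 0.325% (0.228 to 0.450) of UNT cells and 94.8% (94.3 to 95.2) of ERI4 cells. The largest cluster of UNT cells was cluster 1 with 49.3% (48.3 to 50.2), followed by cluster 5 with 30.1% (29.2 to 31.0). The largest of ERI4 cells was cluster 3 with 50.2% (49.2 to 51.2), followed by cluster 2 with 21.1% (20.3 to 21.9), cluster 8 with 16.1% (15.4 to 16.9) and cluster 12 with 7.38% (6.86 to 7.93). The summed overlap of the cluster shares of both conditions was 2.66%. Median pseudotime was 7.59 in UNT cells and 26.6 in ERI4 cells, and the ERI4 cell was higher in 99.2% of random pairs. Untreated cells were the root of this scale, which fixes part of the difference, and the difference of 19.0 shrank to 3.68 when it was taken within each of the 5 clusters with at least 20 cells of both conditions and averaged. Those clusters (1, 6, 9, 11 and 13) held 2.14% (1.86 to 2.46) of ERI4 cells and none of their 4 main clusters, so this value describes few of them. Each cluster counted equally, also cluster 13, which over all conditions had a median of 1102 UMIs and a median mitochondrial share of 68.1%. Cells called S made up 31.3% (30.5 to 32.2) of UNT cells and 21.9% (21.1 to 22.8) of ERI4 cells, while cells called G2M made up 39.7% (38.8 to 40.6) and 38.5% (37.5 to 39.5). These calls also read free RNA and depth, so no rate of division is taken from them.

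**Figure D1:**
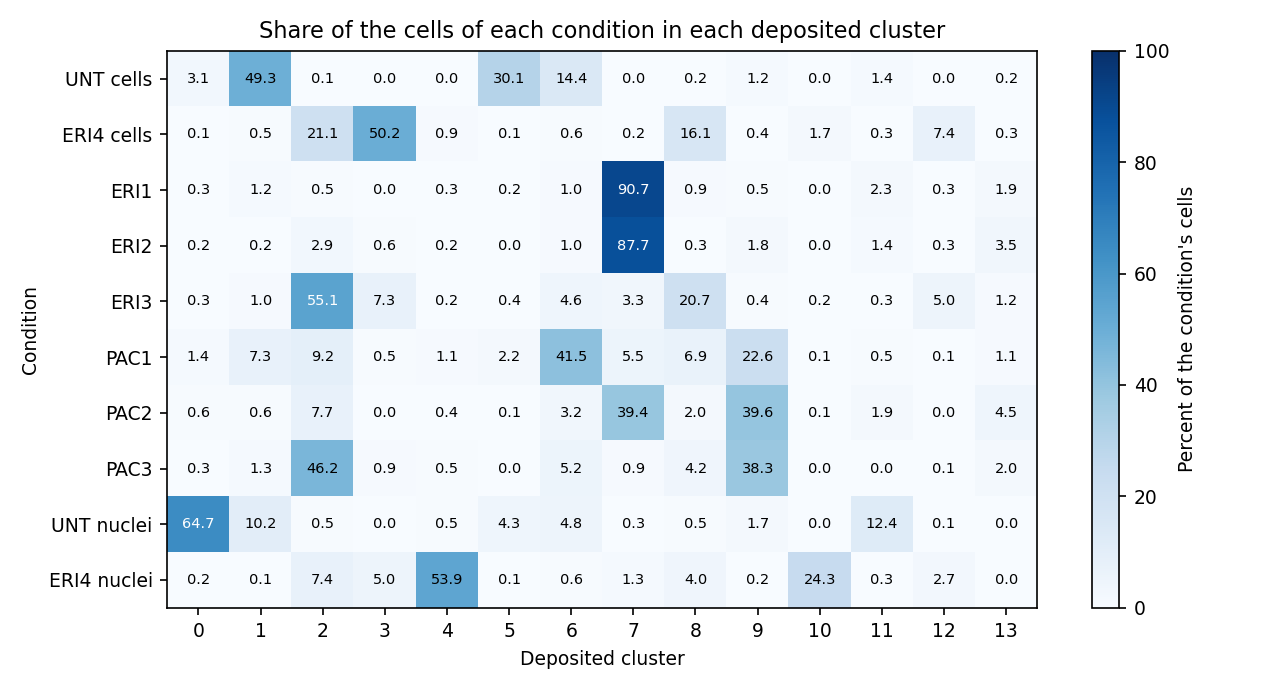
Percent of the cells of each condition (rows) in each of the authors' 14 clusters (columns), 1 library per condition or hashed set, with the value printed in each field. Untreated cells lie mainly in clusters 1 and 5 (49.3% and 30.1%), ERI1 and ERI2 in cluster 7 (90.7% and 87.7%), ERI4 cells in cluster 3 (50.2%), and PAC2 and PAC3 hold 39.6% and 38.3% in cluster 9.

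Nuclei of the same treatments were also apart, mostly in clusters that hardly any whole cells entered. Cluster 0 held 64.7% (63.7 to 65.6) of UNT nuclei, cluster 11 held 12.4% (11.7 to 13) and cluster 1 held 10.2% (9.62 to 10.8). Cluster 4 held 53.9% (52.8 to 54.9) of ERI4 nuclei and cluster 10 held 24.3% (23.5 to 25.3). Of all members of clusters 0 and 4, 93.6% and 95.8% came from the UNT nuclei and ERI4 nuclei libraries. Clusters 2, 3, 8 and 12, which held nearly all ERI4 cells, held 19.0% (18.2 to 19.9) of ERI4 nuclei and 1.01% (0.821 to 1.23) of UNT nuclei, the same direction as in cells. Median pseudotime was 13.3 in UNT nuclei and 22.7 in ERI4 nuclei, and the ERI4 nucleus was higher in 98.6% of pairs. Cluster 4 was shallow, with a median of 1636 UMIs, and its share of ERI4 nuclei was 35.4% among nuclei with at least 1000 genes and 27.5% in the depth window common to both nuclei libraries, where cluster 10 held 35.6%. Chromatin data of these nuclei were not analysed here.

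Cluster 7 held most cells after 1 and 2 rounds of eribulin and few after 3. It held 90.7% (89.3 to 92.0) of ERI1, 87.7% (85.8 to 89.5) of ERI2 and 3.32% (2.71 to 4.01) of ERI3. ERI3 cells lay instead in the clusters also seen in ERI4 cells: 55.1% (53.3 to 56.8) in cluster 2, 20.7% (19.3 to 22.2) in cluster 8, 7.31% (6.42 to 8.29) in cluster 3 and 5.01% (4.26 to 5.84) in cluster 12. The overlap of the cluster shares was 94.0% between ERI1 and ERI2 and 10.8% between ERI2 and ERI3. It was 52.5% between ERI3 and ERI4 cells, which came from different runs. In the UMAP they hardly mixed: 1.16% of the 30 nearest neighbours of ERI3 cells were ERI4 cells. Median pseudotime was 13.6 in ERI1, 13.7 in ERI2 and 22.5 in ERI3, and the ERI3 cell was higher than the ERI2 cell in 90.1% of pairs. The difference of 8.74 between ERI3 and ERI2 was 1.83 when averaged over the clusters with at least 20 cells of both. These clusters (2, 7 and 13) held 94.2% of ERI2 and 59.6% of ERI3. Cluster 13, with its high mitochondrial share, counted as much as clusters 2 and 7. Cells called S made up 24.8% (22.9 to 26.9) of ERI1, 23.9% (21.6 to 26.4) of ERI2 and 19.6% (18.2 to 21.1) of ERI3.

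The main clusters of the paclitaxel conditions changed with each round, and some were also main clusters of eribulin conditions. PAC1 lay mainly in cluster 6, with 41.5% (39.7 to 43.3), and in cluster 9, with 22.6% (21.1 to 24.2). PAC2 lay in cluster 9, with 39.6% (36.3 to 43.0), and in cluster 7, with 39.4% (36.1 to 42.8). PAC3 lay in cluster 2, with 46.2% (44.3 to 48.1), and in cluster 9, with 38.3% (36.5 to 40.2). Cluster 7, the main cluster of ERI1 and ERI2, held 5.46% (4.67 to 6.35) of PAC1 and 0.931% of PAC3. The labels name no recovery after the last round of PAC2, so recovery is not separated from the number of rounds. Median pseudotime was 17.7 in PAC1, 19.6 in PAC2 and 21.6 in PAC3. The later round was higher in only 58.9% of pairs for PAC2 and PAC1 and 57.6% for PAC3 and PAC2. Most PAC2 cells lay on either side of their median, with medians of 13.8 in cluster 7 and 23.9 in cluster 9. The PAC2 median equals that of cluster 13 over all conditions, which held 4.48% of PAC2, so it describes neither of the main PAC2 clusters. Shared clusters (2, 6, 7, 9 and 13) held at least 79.8% of each condition. Averaged over them with equal weight, cluster 13 included, the differences of 1.92 and 1.99 were 0.412 and 0.0620. The former was 3.00 in the common depth window and 0.402 in G1 cells, and the latter 1.04 and 3.11. Cells called S made up 23.7% (22.2 to 25.3) of PAC1, 19.0% (16.4 to 21.8) of PAC2 and 17.8% (16.4 to 19.3) of PAC3.

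At the same number of rounds the drugs differed in different clusters, and their cluster shares overlapped most after 3 rounds. After 1 round the largest differences were in cluster 7 (90.7% of ERI1 against 5.46% of PAC1) and cluster 6 (0.965% against 41.5%). After 2 rounds they were in cluster 7 (87.7% of ERI2 against 39.4% of PAC2) and cluster 9, and after 3 rounds in cluster 9 and cluster 8 (20.7% of ERI3 against 4.15% of PAC3). The overlap of cluster shares between eribulin and paclitaxel was 12% after 1 round, 50.7% after 2 and 60.1% after 3. Cluster 9 held 0.483% (0.221 to 0.914) of ERI1, 1.75% (1.10 to 2.64) of ERI2 and 0.423% of ERI3, against 22.6%, 39.6% and 38.3% of the paclitaxel conditions. Cluster 2 held 55.1% of ERI3 and 46.2% of PAC3. The drugs were in separate libraries of the same run, and the first paclitaxel dose was 100 nM against 500 nM of eribulin. The labels also name no recovery after the last round of PAC2. Drug, dose, library and recovery are therefore not separated. In the UMAP, 22.5% of the 30 nearest neighbours of ERI3 cells were PAC3 cells and 50.9% were ERI3 cells. For ERI1 cells, 27.6% of neighbours were ERI2 cells and 17.3% PAC2 cells. UNT cells and ERI4 cells had 94.2% and 93.7% of their neighbours in their own condition, and UNT nuclei and ERI4 nuclei had 99.4% and 99.2%.

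The number of different barcodes in equal draws fell with rounds of either drug. Barcodes are not a count of lineages, since a lineage with several barcodes can count more than once. Cells with 2 or more detected barcodes made up 59.5% of UNT cells and 39.7% of ERI4 cells. They made up 34.8% of ERI1, 33.6% of ERI2 and 11.3% of ERI3, and 29.7% of PAC1, 31.25% of PAC2 and 18.4% of PAC3. In draws of 569 barcoded cells, UNT cells held a mean of 189 different barcodes (176 to 203 in the central 95% of draws) and ERI4 cells 10.9 (9 to 13). ERI1 held 105 (98 to 112), ERI2 held 53.0 (48 to 58) and ERI3 held 33.4 (27 to 39). PAC1 held 108 (101 to 116), the 569 barcoded cells of PAC2 held 87, and PAC3 held 35.7 (30 to 43). UNT nuclei held 221 (206 to 236) and ERI4 nuclei 35.5 (29 to 42), which became 15.7 with the first revision of the barcode calls. The 10 most frequent barcodes took up 28.9% of the barcoded UNT cells and 99.6% of the barcoded ERI4 cells. A single barcode was called in 46.0% (45.1 to 46.9) of UNT cells and 72.1% (71.1 to 73.0) of ERI4 cells, but in 49.8% (48.8 to 50.8) of UNT nuclei and 17.2% (16.4 to 18) of ERI4 nuclei. These shares depend on the call: with its first revision they were 22.9% in UNT cells, 68.8% in ERI4 cells, 48.9% in UNT nuclei and 48.7% in ERI4 nuclei.

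**Figure D2:**
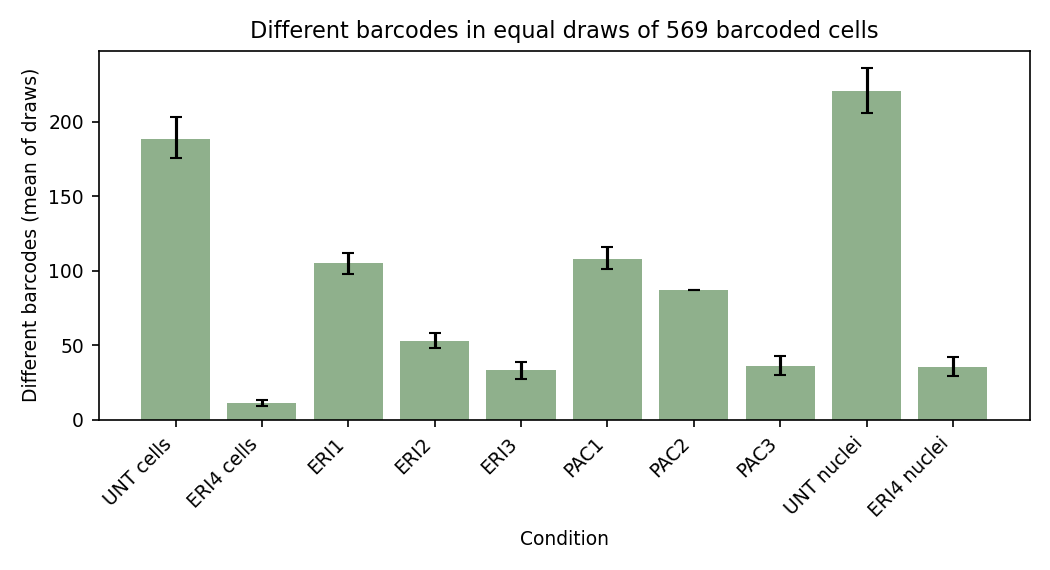
Mean number of different lentiviral barcodes (vertical axis) in 1000 draws of 569 barcoded cells from each condition (horizontal axis); lines span the central 95% of the draws, and PAC2 has none because all of its barcoded cells were drawn. UNT cells and UNT nuclei hold 189 and 221, ERI3 and PAC3 hold 33.4 and 35.7, and ERI4 cells hold 10.9.

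A few barcodes that were rare in untreated cells filled the treated conditions. Barcode bc14-55-bc30-23349, with the sequence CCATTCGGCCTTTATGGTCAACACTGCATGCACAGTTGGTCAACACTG, was carried by 14 of 5087 barcoded UNT cells, 0.275% (0.151 to 0.461), and by 4597 of 6725 ERI4 cells, 68.4% (67.2 to 69.5). It made up 0.369% (0.120 to 0.858) of ERI1, 0.794% (0.320 to 1.63) of ERI2 and 13.8% (12.4 to 15.3) of ERI3, and 0 of 2286 barcoded PAC3 cells, which allows a share of up to 0.131%. In ERI4 nuclei it made up 10.1% (8.62 to 11.7) with the latest call and 75.4% with its first revision. Of the 4245 calls of that revision, 1909 were in nuclei with no detected barcode. Barcode bc14-76-bc30-49517, with the sequence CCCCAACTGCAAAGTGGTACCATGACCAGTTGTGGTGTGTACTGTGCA, was frequent under both drugs. It was carried by 6 UNT cells, 0.118% (0.0433 to 0.257), by 4.20% (3.20 to 5.41) of ERI1, 27.4% (24.5 to 30.5) of ERI2 and 37.9% (35.9 to 39.9) of ERI3, and by 9.15% (7.86 to 10.6) of PAC1, 22.0% (18.6 to 25.6) of PAC2 and 48.9% (46.8 to 51.0) of PAC3. Its share of ERI4 cells, from the other run, was 6.42% (5.85 to 7.04). Barcode bc14-6-bc30-93034, with the sequence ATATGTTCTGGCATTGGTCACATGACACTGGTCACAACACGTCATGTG, rose from 0.295% (0.165 to 0.486) of UNT cells to 9.92% (9.21 to 10.7) of ERI4 cells and made up 25% (23.2 to 26.9) of ERI3 and 7.22% (6.19 to 8.36) of PAC3.

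Other barcodes had their highest shares under paclitaxel, in ERI2 or in untreated cells. Barcode bc14-4-bc30-67693 made up 2.90% (2.17 to 3.79) of PAC1, 7.21% (5.22 to 9.65) of PAC2 and 21.3% (19.6 to 23.0) of PAC3, and 0 of 2215 barcoded ERI3 cells, which allows a share of up to 0.135%. Barcode bc14-18-bc30-67263 made up 3.96% (3.11 to 4.97) of PAC1 and 6.50% (4.62 to 8.85) of PAC2 but 0.131% of PAC3. Barcodes bc14-22-bc30-18173 and bc14-55-bc30-37135 made up 14.1% (11.8 to 16.5) and 9.07% (7.26 to 11.2) of ERI2, but 0.722% and 0.813% of ERI3; in PAC1 they made up 0.502% and 0.112%. The most frequent barcodes of UNT cells, bc14-30-bc30-58918 with 5.15% (4.56 to 5.79) and bc14-22-bc30-14328 with 4.91% (4.34 to 5.54), were in 0 of 6725 barcoded ERI4 cells, which allows a share of up to 0.0446% each, and the latter made up 0.558% of PAC1. Of the 68 barcodes with at least 20 cells over UNT and ERI4 cells, 59 were seen in UNT cells alone and 2 in ERI4 cells alone. ERI3 shared 13 of its 63 barcodes with PAC3, and these held 74.7% of its barcoded cells and 59.1% of those of PAC3.

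**Figure D3:**
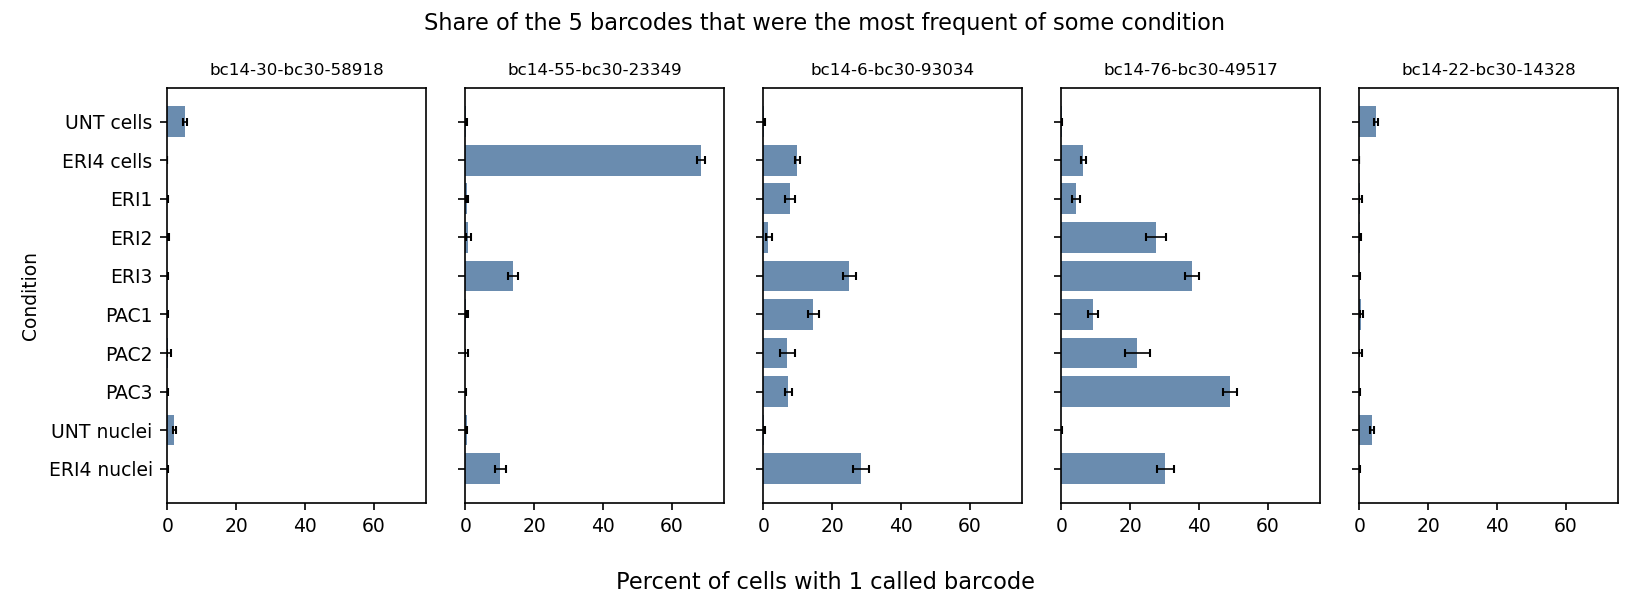
Percent of barcoded cells (horizontal axis, bars, with exact 95% intervals as lines) that carry each of the 5 barcodes that were the most frequent of some condition, by condition (vertical axis). bc14-55-bc30-23349 reaches 68.4% in ERI4 cells and bc14-76-bc30-49517 reaches 37.9% in ERI3 and 48.9% in PAC3, while both barcodes most frequent in the untreated libraries are near 0 after treatment.

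Cells of the same lineage lay in the same cluster more often than shuffled clusters gave in UNT cells, with 84.6% of pairs against 42.5%, in ERI4 cells, with 92.4% against 50.0%, in ERI3, with 81.3% against 31.0%, and in PAC3, with 86.9% against 38.3%. In ERI1 and ERI2, where nearly all cells were in cluster 7, the values were 86.1% against 84.7% and 84.5% against 82.2%. PAC1 gave 40.1% against 22.0% and PAC2 53.4% against 32.9%. In nuclei the values were closer, with 53.0% against 47.0% in UNT nuclei and 31.6% against 28.8% in ERI4 nuclei. The values in ERI3 and ERI4 depended on the frequent barcodes: among barcodes with 2 to 20 cells they were 30.8% against 31.1% in ERI3, 58.3% against 48.9% in ERI4 cells and 23.3% against 28.6% in ERI4 nuclei. Of the cells with bc14-55-bc30-23349, 71.4% (41.9 to 91.6) lay in cluster 1 in UNT cells and 96.4% (95.8 to 96.9) in cluster 3 in ERI4 cells. Of the cells with bc14-76-bc30-49517, 89.5% (78.5 to 96.0) lay in cluster 7 in ERI1 and 89.3% (84.7 to 92.9) in ERI2, but 93.0% (91.0 to 94.6) in cluster 2 in ERI3 and 92.5% (90.8 to 94.0) in PAC3. Of the cells with bc14-6-bc30-93034, 90.4% (83.0 to 95.3) lay in cluster 7 in ERI1, and 89.7% (86.9 to 92.1) in cluster 8 in ERI3. Cells with bc14-95-bc30-33662 lay in cluster 8 in ERI4 cells, with 90.5% (88.2 to 92.6), and cells with bc14-39-bc30-41529 in cluster 12, with 96.5% (91.2 to 99.0). Cells with bc14-4-bc30-67693 lay in cluster 9 in PAC3, with 99.0% (97.6 to 99.7).

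**Figure D4:**
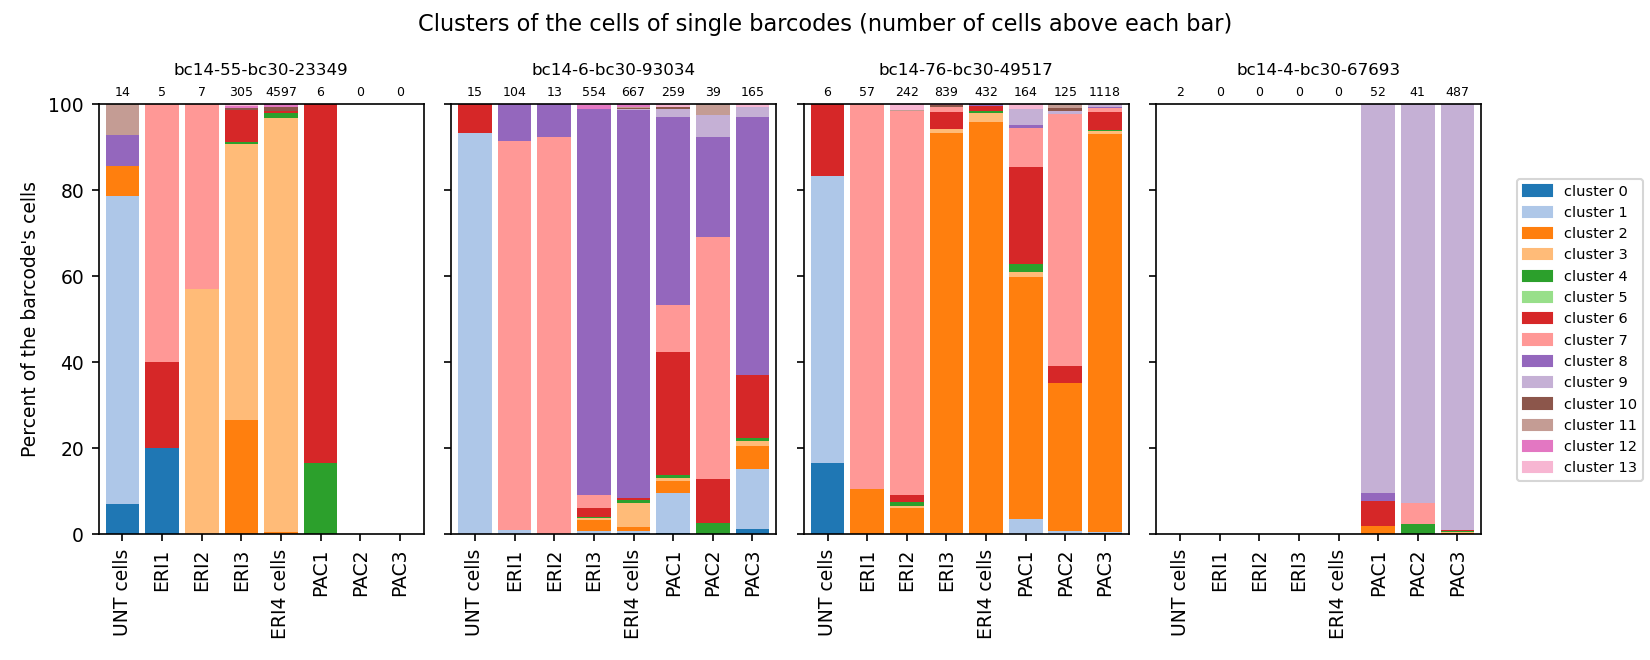
Cluster makeup (stacked bars, percent of the barcode's cells on the vertical axis) of 4 frequent barcodes in UNT cells, ERI1 to ERI3, ERI4 cells and PAC1 to PAC3 (horizontal axis); the number of cells stands above each bar and no bar is drawn below 5 cells. bc14-76-bc30-49517 lies mainly in cluster 7 in ERI2 (89.3%) and in cluster 2 in ERI3 (93.0%), and bc14-6-bc30-93034 in cluster 7 in ERI1 (90.4%) and in cluster 8 in ERI3 (89.7%).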

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

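The tests in this part were chosen after the results were seen. The change in a quantity was compared between cells and nuclei or between the drugs, each with 1 library per condition. Of 29 such comparisons, 7 went in opposite directions, some of them for the same quantity. A share counted only if both changes were at least 1 percentage point. None of these differences was tested. Median UMIs per cell were 2457 higher in ERI4 cells than in UNT cells, and the ERI4 minus UNT difference in nuclei was -1338.5. Median genes per cell likewise differed by 349 in cells and by -560.5 in nuclei. From round 1 to round 3 the median number of UMIs fell by 6030.5 with eribulin and was 1101.5 higher with paclitaxel, and the median number of genes fell by 897 with eribulin and was 135.5 higher with paclitaxel. Over the same rounds the share in cluster 6 rose by 3.68 percentage points with eribulin and fell by 36.3 with paclitaxel, and the share in cluster 8 rose by 19.8 with eribulin and fell by 2.78 with paclitaxel.

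The share with a single called barcode was 26.1 percentage points higher in ERI4 cells than in UNT cells and fell by 32.6 in nuclei. Along with it, barcode bc14-55-bc30-23349 made up 68.4% of barcoded ERI4 cells but 10.1% of barcoded ERI4 nuclei. A candidate explanation is that the latest call left nuclei of the most frequent barcode without a call. Of its 151 called ERI4 nuclei, 80.1% lay in cluster 10 and 7.28% in cluster 3, its cluster in cells. A further 2977 ERI4 nuclei, 34.2% (33.2 to 35.2), had 1 detected barcode and no call. They made up 56.9% (52.1 to 61.6) of the nuclei in cluster 3, against 18.8% (16.4 to 21.3) in clusters 2 and 8 of the next barcodes. Uncalled nuclei with 1 detected barcode were not compared in clusters 4 and 10, which held most ERI4 nuclei. In UNT nuclei all 159 such nuclei carried bc14-30-bc30-58918, the most frequent barcode of UNT cells, in the first revision of the call, and adding them moved its share of nuclei from 2.03% to 5.08%, against 5.15% (4.56 to 5.79) in cells; if all 2977 ERI4 nuclei carried bc14-55-bc30-23349, its share would be 69.9%, although the first revision, which is out of step with the latest call in this library, gave it to 1063 of them. A different mix of clones in the culture used for nuclei stays open, since among nuclei without that barcode bc14-95-bc30-33662 made up 14% (12.2 to 16.0) against 33.8% (31.8 to 35.8) in cells and bc14-76-bc30-49517 33.6% (31.1 to 36.2) against 20.3% (18.6 to 22.1), which the call could also produce, while bc14-6-bc30-93034 made up 31.6% (29.1 to 34.2) against 31.3% (29.4 to 33.4).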

How the results depend on the processing

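Of the values that the main results took under the alternatives, 99 stayed within the counting interval (for pairs of the same barcode, an interval with each barcode counted as 1 observation, which is wide where barcodes are few; for numbers of barcodes, a factor of 1.5), 64 left it and 2, both for pairs of the same barcode, turned direction; 2 further differences, of pseudotime between the drugs, also turned. The cause was not tested for any of them. With at least 1000 genes per cell the share in cluster 7 was 92.3% in ERI1 and 90.6% in ERI2, in cluster 0 of UNT nuclei 66.0% and in cluster 4 of ERI4 nuclei 35.4%; fewer shallow cells are in these sets by construction. In the common depth window the cluster that was largest among all cells of a condition held 51.6% of ERI4 cells, 93.5% of ERI1, 90.8% of ERI2, 59.3% of ERI3, 44.4% of PAC1, 46.1% of PAC2, 48.6% of PAC3, 63.1% of UNT nuclei and 27.5% of ERI4 nuclei, where cluster 10 was then larger; S calls were 35.1% of UNT cells and 24.4% of ERI4 cells, and a single barcode was called in 48.2% of UNT cells, 75.1% of ERI4 cells and 18.9% of ERI4 nuclei. The authors' stated filter, added after seeing the data, gave 90.1% of ERI2 in cluster 7, and leaving out cells called Doublet or Multiplet, also added, gave 48.7% of PAC3 in cluster 2 and 63.6% of UNT nuclei in cluster 0. The pseudotime difference of ERI4 and UNT was 18.8 by means, 19.3 in the depth window, 20.8 in G1 cells and 3.68 within shared clusters for cells, and 9.73 by means and 11.3 in the depth window for nuclei. ERI1 minus PAC1 turned to 0.598 within shared clusters and ERI3 minus PAC3 to -0.0164 by means.

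The other barcode calls, added after seeing the data, name fewer cells in most conditions. The first revision called a single barcode in 22.9% of UNT cells, 68.8% of ERI4 cells and 48.7% of ERI4 nuclei, and the first call in 18.6%, 58.5%, 5.15% and, for UNT nuclei, 24.9%. The share of the barcode that was largest in each condition with the latest call was, with the first revision, 6.99% in UNT cells, 70.0% in ERI4 cells, 30.9% in ERI2, 16.6% in PAC1, 52.8% in PAC3 and 8.53% in ERI4 nuclei. With the first call it was 7.39% in UNT cells, 79.4% in ERI4 cells, 9.42% in ERI1, 32.7% in ERI2, 40.5% in ERI3, 18.4% in PAC1, 26.7% in PAC2, 53.7% in PAC3, 2.67% in UNT nuclei and 14.7% in ERI4 nuclei. Draws from PAC3 held 22.5 barcodes with the first call, and draws from ERI4 nuclei 15.7 with the first revision. ERI4 and UNT nuclei shared 58 barcodes, 19 with at least 2 cells in each and 18 with the first call. Pairs of the same barcode in the same cluster made up 68.9% in UNT cells, 58.3% in ERI4 cells, 55.4% in PAC1 and 76.6% in PAC2 among barcodes with 2 to 20 cells; there, ERI3 at 30.8% and ERI4 nuclei at 23.3% lay below their shuffled values of 31.1% and 28.6%. With barcodes weighted equally the values were 68.3% in UNT cells, 70.6% in ERI4 cells (within the interval of its 13 barcodes), 44.3% in ERI3, 51.5% in PAC1, 69.7% in PAC2 and 54.0% in PAC3, and UNT nuclei gave 58.0% with the first revision. Other cluster columns were identical, every barcode of the latest call was single and in the reference list, and hashtag singlets are not marked. Those alternatives therefore changed nothing or were not run, and calls with too few barcoded cells gave no draw. In UNT nuclei the first call and its first revision joined several barcodes in 612 nuclei, and the latest call left 56 unmapped. The nuclei are shallower than the cells, with median UMI counts of 3428 and 2089.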

Other observations

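The tests in this part were chosen after the results were seen. The untreated libraries of runs 1 and 3 held much the same lineages: 341 barcodes were in both, they made up 95.5% of barcoded UNT cells and 92.6% of barcoded UNT nuclei, and the summed overlap of barcode shares was 73.1%. Across these 341 barcodes, which are not independent replicates, the Spearman correlation of cell numbers was 0.765. For ERI4 cells and ERI4 nuclei 14 barcodes were in both, with an overlap of 41.1% with the latest call. This overlap depends on the call. Barcode bc14-55-bc30-23349, with 68.4% of barcoded ERI4 cells, made up 10.1% of ERI4 nuclei with the latest call and 75.4% with its first revision. That revision made 4245 calls in this library, 1909 of them in nuclei with no detected barcode.

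Barcodes grouped by their cluster before treatment had shares in ERI3, ERI4 cells and PAC3 that rested on few of them, less so after 1 round. Of the barcodes with at least 10 UNT cells, 61 lay mainly in cluster 1, 29 in cluster 5 and 13 in cluster 6. Barcodes with fewer UNT cells are in no group, also where they were frequent later. Barcode bc14-76-bc30-49517 had 6 UNT cells, 4 of them in cluster 1, and made up 27.4% of ERI2, 37.9% of ERI3 and 48.9% of PAC3. Barcode bc14-95-bc30-33662 had 8 UNT cells, 7 of them in cluster 1, and made up 10.7% of ERI4 cells. The group shares that follow leave both out. Where a share is given without a barcode, that barcode's cells are left out of the total as well. The 61 barcodes of cluster 1 made up 47.2% (45.9 to 48.6) of barcoded UNT cells, 35.6% (33.1 to 38.2) of ERI1, 5.10% (3.75 to 6.77) of ERI2, 39.8% (37.8 to 41.9) of ERI3 and 78.3% (77.3 to 79.3) of ERI4 cells, and 26.7% (24.6 to 28.8) of PAC1, 14.4% (11.6 to 17.6) of PAC2 and 8.14% (7.05 to 9.33) of PAC3. In ERI1 31 of them were seen, and without the largest the share was 30.3% (27.7 to 32.9). In ERI4 cells only 2 of them were seen, bc14-55-bc30-23349 with 4597 and bc14-6-bc30-93034 with 667 of the 5264 cells. The 667 cells were 31.3% (29.4 to 33.4) of the 2128 barcoded ERI4 cells without bc14-55-bc30-23349, and 9.92% of all 6725. Without bc14-6-bc30-93034 the group made up 19.7% (17.9 to 21.7) of ERI3, 14.3% (12.6 to 16.1) of PAC1, 8.11% (5.93 to 10.8) of PAC2 and 0.990% (0.614 to 1.51) of PAC3. The 29 barcodes of cluster 5 made up 23.2% (22.0 to 24.4) of UNT cells, 26.6% (24.3 to 29.1) of ERI1, 42.2% (38.9 to 45.5) of ERI2, 7.99% (6.90 to 9.20) of ERI3 and 1.74% (1.44 to 2.08) of ERI4 cells, and 6.19% (5.12 to 7.41) of PAC1, 2.46% (1.35 to 4.09) of PAC2 and 0.131% of PAC3. Of these, bc14-39-bc30-41529 held 113 of the 117 ERI4 cells and 104 of the 177 ERI3 cells, and without it the group made up 0.0605% of ERI4 cells, 3.46% (2.72 to 4.33) of ERI3 and 21.7% (19.4 to 24.0) of ERI1. Without bc14-22-bc30-18173 it made up 32.7% (29.4 to 36.2) of ERI2. The 13 barcodes of cluster 6 made up 9.89% (9.08 to 10.7) of UNT cells, 3.39% (2.49 to 4.50) of ERI1 and 0.181% of ERI3, and 8.37% (7.13 to 9.75) of PAC1, 2.99% (1.75 to 4.74) of PAC2 and 1.66% (1.18 to 2.27) of PAC3, the last 0.619% (0.339 to 1.04) without the largest, bc14-92-bc30-83570. They were in 0 of 882 barcoded ERI2 cells, which allows a share of up to 0.340%, and 0 of 6725 ERI4 cells, which allows up to 0.0446%.

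Within lineages, cells lay in cluster 7 after 2 rounds of eribulin and elsewhere after 3. Of the barcodes, 9 had at least 10 cells in both ERI2 and ERI3. Their median cluster 7 share was 94.7% in ERI2 and 3.85% in ERI3, with a highest value of 31.25% in ERI3. A change in which barcodes were present therefore does not account for this fall. Depth does not either. In the common depth window of 8179.2 to 19690.5 UMIs, cluster 7 held 89.9% (87.2 to 92.2) of ERI2 and 1.93% (1.39 to 2.59) of ERI3. Cells called Doublet or Multiplet were 11.2% (10.1 to 12.5) of the cluster 7 cells of ERI1 and ERI2, against 6.71% (4.25 to 9.98) of their other cells. That is with the latest call, which named 8.47% of ERI1 and 11.5% of ERI2 Doublet. Its first revision named 27.0% and 27.8%. These values cannot tell movement of cells from growth of cells of the same barcode that already lay elsewhere. In ERI2, 15 of the 242 cells with bc14-76-bc30-49517 lay in cluster 2, while all 80 with bc14-55-bc30-37135 lay in cluster 7. The rounds were captured in the same library, so capture and sequencing are shared. Differences between the cultures at harvest cannot be separated from the number of rounds. PAC2, for which the labels name no recovery after its last round, also held 39.4% in cluster 7. There 18.3% (14.3 to 22.8) of its cells were called Doublet or Multiplet against 9.14% (6.80 to 12) of its other cells. Of the cells with bc14-76-bc30-49517, 9.15% lay in cluster 7 in PAC1, 58.4% in PAC2 and 0.984% in PAC3. Over the 12 barcodes with at least 10 cells in both PAC1 and PAC2, the median share was 0% and 4.82%. This median hides a split. Barcodes that lay mainly in cluster 9 in both conditions had at most 4.88% in cluster 7 in PAC2. All the others had at most 10.8% there in PAC1 and 56.4% to 88.9% in PAC2. No biological explanation was tested.

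Cluster 9, large after paclitaxel, was already present in untreated cells, with 1.24% (1.04 to 1.46) of UNT cells and 1.71% (1.47 to 1.99) of UNT nuclei. Of 62 barcodes with at least 10 cells over PAC1 to PAC3, 20 had most of these cells in cluster 9. Of these 20, 10 were seen in 53 untreated cells and nuclei, and 45 of the 53, 84.9% (72.4 to 93.3), were in cluster 9. With other barcodes it was 51 of 9969, 0.512% (0.381 to 0.672), which argues against an effect of the run, although these 51 outnumber the 45. Cells of 1 lineage are not independent, and bc14-18-bc30-67263 alone gave 6 UNT cells and 16 UNT nuclei in cluster 9. Carry-over of paclitaxel cells would also have brought bc14-76-bc30-49517 cells of cluster 2, of which none were seen (exact Poisson upper bound 3.69) where the paclitaxel conditions gave an expectation of at least 9.13. These 20 barcodes made up 0.413% (0.256 to 0.630) of barcoded UNT cells, 0.590% (0.255 to 1.16) of ERI1, 1.93% (1.13 to 3.07) of ERI2 and 0.451% (0.217 to 0.829) of ERI3; their share after paclitaxel follows from how they were chosen and is no test.

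A further test took barcodes by the clusters of their untreated cells and nuclei: 7 of 468 barcodes with at least 2 of these had most of them in cluster 9. Cluster 9 itself was made on all libraries together. Its 2472 cells include 662 of PAC1, 336 of PAC2 and 1070 of PAC3, so the choice is not free of the paclitaxel data. These 7 made up 0.559% (0.422 to 0.725) of barcoded untreated cells and nuclei, 11.2% (9.74 to 12.7) of PAC1, 19.9% (16.7 to 23.4) of PAC2 and 23.1% (21.4 to 24.9) of PAC3, and 6 of them were seen in at least 1 of these conditions. They made up 0.221% (0.0456 to 0.645) of ERI1, 0 of 882 barcoded ERI2 cells, which allows a share of up to 0.340%, and 0 of 2215 ERI3 cells, which allows up to 0.135%. The largest, bc14-4-bc30-67693, was then left out of both the group and the totals. The others made up 0.539% (0.405 to 0.703) of untreated, 8.51% (7.24 to 9.92) of PAC1, 13.6% (10.8 to 16.9) of PAC2 and 2.33% (1.69 to 3.14) of PAC3. This is consistent with the hypothesis that lineages already in cluster 9 made up more of the cells after paclitaxel, but untreated and paclitaxel libraries differ in run, and whether the drug, the dose or chance in 1 culture brought it about was not tested.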
